A study of Mus musculus with 4 samples.

How the data were processed

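Female MMTV-PyMT mice were studied at an age of 10 weeks, and their lungs were profiled as whole cell suspensions with the Chromium single-cell 3' assay. MMTV-PyMT mice carry the polyoma middle T oncogene under a mammary promoter and develop mammary tumours. There were 4 samples, 2 from untreated controls and 2 from mice under 4 weeks of chronic mild unpredictable stress, each deposited as 1 library. Per the labels' protocols, the tissue was digested with enzymes at 37 °C for 30 min and passed through a 40 µm strainer. Living cells were then marked with acridine orange and propidium iodide and sorted, with 20000 to 30000 cells targeted per library. A depth of about 200000 reads per cell was aimed at. All 4 samples carry the same batch label, so no within-batch value differs from the pooled one. The labels do not say whether replicates are separate mice or pools, so every p-value measures only the spread between these samples.

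The deposited matrices hold UMI counts, whole numbers per gene and barcode that the authors left unnormalized. Cell Ranger 5.0.0, bcl2fastq 2.20 and Seurat 4.3.0 are named in the submitters' processing notes, with the builds mm10 and GRCm38, but the notes give no role for each. Of the 32286 gene identifiers, 32158 (99.6%) are in the GRCm38 reference annotation used here for coordinates. Gene length below means the genomic span from a gene's start to its end, introns included, and transcript length was not examined. The matrices held 25523 and 21767 barcodes for the controls and 17506 and 15139 for the stress libraries, and the smallest barcode in each had 500 UMIs. No cell annotation was used here, so cell classes were rebuilt from the counts.

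Barcodes with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. Doublets were called per library with scrublet through scanpy 1.11.5 and removed. They made up 10.4% and 17.7% of the filtered barcodes in the controls and 6.84% and 7.61% in the stress libraries. Cells were clustered on 2000 variable genes and 40 principal components with 15 neighbours, without integration, using Leiden at resolution 1.0 (leidenalg 0.10.2, Python 3.11.15). This gave 60 clusters. A cluster took the name of the class whose fixed markers averaged a log2 fold of at least 1.5 over the other cells. At least 3 of these markers had to reach a log2 fold of 1.0, and the cluster had to hold at least 20 cells. Markers of every other lineage had to average below 1.0. Cycling cells can belong to any lineage, so the cycling class was exempt from this last limit. A pseudocount of 20 CPM entered these folds. A cluster stayed unnamed if its 10 leading genes held more markers of another class of its lineage than of its own. A further rule on low UMI counts left no cluster unnamed under these settings. In all, 18 clusters (2442 of 64531 cells) stayed unnamed, which were 5.73% and 1.17% of the control and 2.06% and 5.61% of the stress cells. The other clusters formed 24 classes.

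The markers, the gene lists, the tests and the rule for named genes were fixed before the data were examined. The naming thresholds and the merging of the 2 types of conventional dendritic cell and of the 2 types of monocyte were set after the clusters had been seen. One naming rule was relaxed later. The first form compared a cluster's leading genes with every class rather than with its own lineage, and it left the neutrophil cluster of the stress libraries unnamed when doublets were kept or filters were stricter. Classes under the settings above are identical with both forms.

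Counts were summed per class and library. Each class with at least 20 cells in every library was tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, TMM scaling, filterByExpr, no block) at a Benjamini-Hochberg adjusted p of 0.05, with DESeq2 1.42.0 as the other tool. Every adjusted p of a gene given without a tool comes from edgeR. Cell numbers per class were tested with the same edgeR test on all cells of a library and with two-sided exact permutation tests, whose p cannot go below 0.333 with 2 against 2. Gene lists with at least 4 tested members were tested with limma's camera (limma 3.58.1, preset correlation 0.01) on voom values, adjusted over the lists of a class, with the estimated correlation and fry beside it. With 2 against 2 libraries the estimated correlation rests on few residuals, and camera has little power with it. Fry asks whether a list's genes move on balance one way and compares them with no other genes. Lists called foreign hold markers of other cell types.

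In neutrophils up to 12 higher and 12 lower genes are named. These have an adjusted p under 0.05, a mean of at least 10 CPM, groups that do not overlap, and the largest log2 folds. A fixed set of neutrophil, glucocorticoid and interferon genes is always given, of which Ifit3 was not tested because of low counts. A gene of this set and a gene of a list are not reported here. In other classes up to 3 genes per direction are named by the same rule, and for lists up to 4 members with the smallest p. Genes with near-identical copies (Hba-a1 and Hba-a2, Hspa1a and Hspa1b, Ccl21a, the class I MHC genes) may share reads with them, so their separate values are uncertain. The 3' kit and the counting are not stated to use strand, so overlapping genes may share reads as well.

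Tests were checked on simulated counts. The changed genes, 100 for each fold, were drawn from genes with a mean of at least 10 CPM. For the neutrophil comparison (7707 genes), 26% of genes changed 2-fold and 92% of those changed 4-fold were recovered, with 14 false calls. For T cells (10592 genes) the shares were 66% and 99%, with 13 false calls. A share's 95% interval is the exact binomial one, and a count of 0 allows 3 counts. Both cover counting error only.

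Alternatives covered the scaling, the tool, the low-count filter, a replicate block, each library left out in turn, doublets kept, stricter cell filters (1000 UMIs, 5% mitochondrial), Leiden resolution 2.0, thinning, and leaving out markers of other cell types. For shares they covered the denominator and TMM over classes. With 1 library left in a group, its spread is assumed to be that of the other group. The test of whether stress effects differ between neutrophils and monocytes was not run, since the monocyte class held 122 and 393 control cells and only 1 and 18 stress cells.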

Results

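Single-cell RNA profiles were collected from the lungs of tumour-bearing MMTV-PyMT mice, with 2 control libraries and 2 libraries of mice under chronic stress (daily noise, restraint, elevated platform, shaking or tail clamping at unpredictable times). The series concerns lung metastasis and neutrophil differentiation under stress. Total depth was even, with 77418888 and 78787668 UMIs in control replicates 1 and 2 and 77664167 and 83839876 in stress replicates 1 and 2. After filtering, 21327 and 15838 control cells and 14127 and 13239 stress cells remained. Median UMIs per barcode before filtering were 2101 and 2569 in the controls and 2559.5 and 2179 under stress. What the UMIs covered was less even. The beta-globin gene Hbb-bs took 20.6% and 29.1% of all UMIs in the stress libraries, against 3.96% in control 1, and in control 2 the leading gene was the surfactant gene Sftpc with 6.96%. The 10 most abundant genes of each library held 18.7% and 20.7% of control UMIs and 50.5% and 58.9% of stress UMIs.

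The first comparison asked whether the cell makeup of the lung differed under stress. Neutrophils made up 5.13% and 17.9% of control cells and 35.6% and 9.37% of stress cells, or 11.5% ± 9.02 against 22.5% ± 18.5 (SD, n = 2 each). The libraries of the 2 groups overlapped. The log2 fold was 0.97 (SE 1.35, adjusted p = 0.966 in edgeR). It turned to −0.30 without stress replicate 1, and was 0.33 without control 1, 2.13 without control 2 and 1.63 without stress replicate 2. The two-sided exact permutation p was 0.667, where 2 against 2 allows no value below 0.333. Alveolar macrophages, the resident phagocytes of the airspace, made up 1.29% and 5.75% of control cells and 0.340% and 0.0453% of stress cells (log2 fold −4.18, adjusted p = 0.130). Monocytes made up 0.572% and 2.48% against 0.00708% and 0.136% (log2 fold −4.41, adjusted p = 0.130). Erythroid cells made up 1.20% and 0.732% against 4.83% and 4.92% (log2 fold 2.34, adjusted p = 0.583), and T cells 31.7% and 10.6% against 6.38% and 34.0%. None of the 24 classes passed in edgeR (0 calls), with 2 classes, the macrophages and monocytes, at an unadjusted p under 0.05. Both passed at an adjusted p of 0.0319 with doublets kept. Exact 95% intervals for the neutrophil share were 4.84% to 5.43% and 17.3% to 18.5% in the controls and 34.8% to 36.4% and 8.88% to 9.88% under stress, far narrower than the differences within groups. All shares follow a sort of living cells by acridine orange and propidium iodide, which can set them. Under the first, unrelaxed naming rule the neutrophil log2 fold was −3.51 (adjusted p = 0.0434) with doublets kept and −2.74 (adjusted p = 0.546) with stricter filters. That rule named 1004 and 2859 control and 213 and 38 stress neutrophils with doublets kept, where the relaxed one named 1091 and 2871 against 5044 and 1217.

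**Figure D1:**
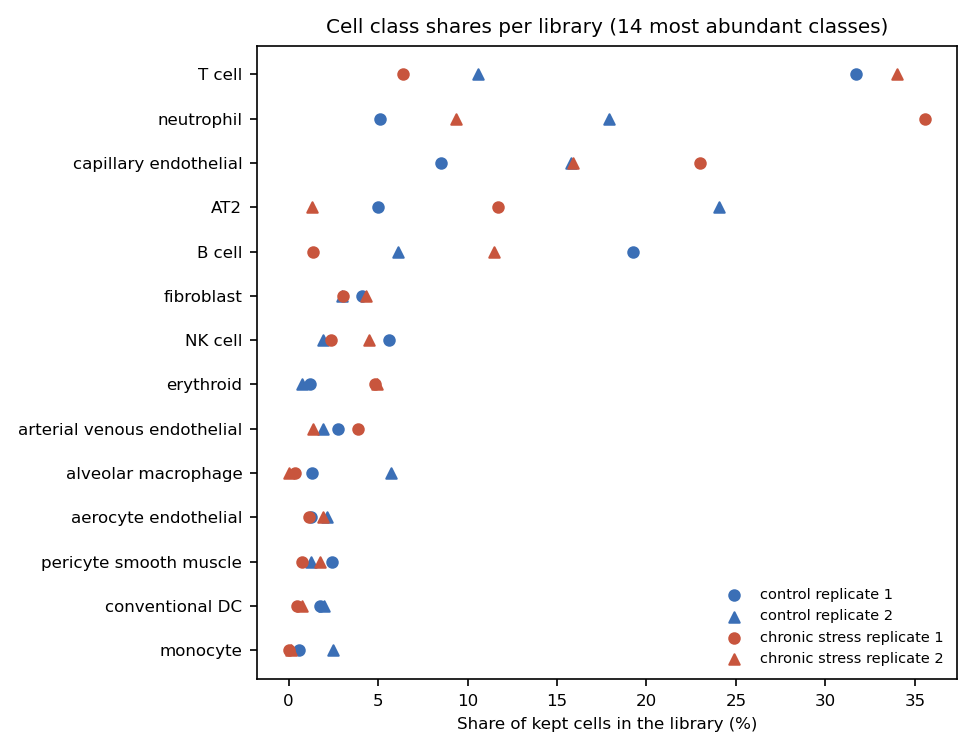
Share of kept cells (%, horizontal axis) in the 14 most abundant cell classes (vertical axis), 1 point per library, with blue for control and red for chronic stress, circles for replicate 1 and triangles for replicate 2. Neutrophils spread from 5.13% to 35.6% with overlapping groups, while erythroid cells sit near 4.83% and 4.92% under stress and at 1.20% and 0.732% in the controls.

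Neutrophils of the 2 groups fell mostly into different clusters. Cluster 5, led by Cxcr2, Il1b and Csf3r, held 996 and 2695 control cells and 45 and 34 stress cells. Cluster 1, led by the inflammatory genes Cxcl2, Hcar2 and Ccrl2, held 82 and 16 control cells and 4823 and 1205 stress cells. A small cluster, number 28, led by the granule genes Camp, Ngp and Ltf, held 16 and 121 control cells and 158 and 2 stress cells. Such a split was also seen in other classes. Capillary endothelial cells lay in cluster 4 (1499, 2420, 203 and 70 cells in controls 1 and 2 and stress replicates 1 and 2), cluster 6 (314, 23, 2984 and 77) and cluster 10 (7, 53, 64 and 1956). T cells included cluster 3 (3837, 928, 84 and 200) and cluster 7 (122, 10, 328 and 2163), where the heat shock gene Dnajb1 was among the leading genes. No integration was applied, so clusters can hold differences between libraries, and cluster sizes were not tested.

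The main comparison asked which genes differed in neutrophils. Of 7707 genes tested, 279 were higher and 96 lower under stress. At an unadjusted p under 0.05 in edgeR 967 were higher and 874 lower, and the median log2 fold over all tested genes was −0.06. The neutrophil chemokine genes Cxcl3 (log2 fold 4.04, SE 0.29, adjusted p = 0.00308) and Cxcl1 (3.43, adjusted p = 0.00802) rose. Cxcl3, on chromosome 5 at 90786103 to 90789600 of GRCm38, stood at 43.2 and 46.5 CPM in the controls and at 673 and 805 CPM under stress. The interleukin gene Il1a (3.72), the tissue factor gene F3 (3.60), the granulocyte growth factor gene Csf3 (3.51), the thrombospondin gene Thbs1 (3.48) and Schip1 (3.32), Ifrd1 (3.24) and the heat shock gene Hspb1 (3.22) rose too. Of the genes that fell and had a mean of at least 10 CPM, Cbfa2t3 (−3.29), Ube2l6 (−3.00) and the immediate early transcription factor gene Egr1 (−2.64, SE 0.28, adjusted p = 0.00484) had the largest log2 folds. Egr1, on chromosome 18 at 34859823 to 34864984, went from 614 and 617 CPM to 113 and 83.2 CPM. Other genes that fell were the fatty acid desaturase gene Scd1 (−2.50), Gm28192 (−2.21), Zfp217 (−2.13), Gpr146 (−2.09), Pptc7 (−1.96), Tirap (−1.93), E230029C05Rik (−1.93), Rassf4 (−1.92) and Nfic (−1.86). Csf3 had 0 and 15 UMIs in the controls and 161 and 25 under stress, so its fold rests on few control UMIs and was 9.06 without control 2. Scd1 was −1.63 without control 2, where its call ended (adjusted p = 0.458). The remaining genes named as higher were the lymphatic chemokine gene Ccl21a (5.35, 1 and 4 UMIs in the controls and 91 and 86 under stress), Proscos (3.95) and the globin gene Hba-a1 (3.18).

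All 375 called genes had groups that did not overlap. A call with 2 against 2 nearly requires this, so it adds no support, and the 33.3% that chance gives holds only for unselected genes. DESeq2 called 390 higher and 49 lower, so that 88.8% of its calls were higher against 74.4% in edgeR, or 80.8% in edgeR with DESeq2's size factors. The counts depended on the libraries, with 269 higher and 138 lower without control 1, 45 and 7 without control 2, 574 and 341 without stress replicate 1, and 998 and 505 without stress replicate 2. The naming rule was relaxed after results had been seen, and the settings above give the same classes under both forms. Under its first, unrelaxed form 287 were higher and 136 lower (67.8% higher) with doublets kept. With stricter filters 423 were higher and 530 lower (44.4% higher), where that form named 381 and 32 stress neutrophils and the relaxed one 4384 and 1004. Without control 2 these calls ended, with adjusted p in brackets: Cxcl1 (0.0539), Hba-a1 (0.302), Cbfa2t3 (0.158), Scd1 (0.458), Gm28192 (0.383), Zfp217 (0.0936), Tirap (0.296), Rassf4 (0.383) and Nfic (0.0936). With the gene length trend removed, a correction chosen after the data were seen, the calls of 5 of the 24 named genes ended at folds of similar size: Csf3 (log2 fold 3.51 to 3.25, adjusted p = 0.0563 after), Scd1 (−2.50 to −2.50, 0.0638), Tirap (−1.93 to −1.91, 0.0606), E230029C05Rik (−1.93 to −1.71, 0.0606) and Rassf4 (−1.92 to −1.78, 0.0643). All 134 ended neutrophil calls had a median absolute log2 fold of 1.36 before and 1.27 after (SE 0.30 and 0.29). Further calls that ended were Csf3 (0.0511), Cbfa2t3 (0.138) and Rassf4 (0.110) at Leiden resolution 2.0, Csf3 (0.0880), Scd1 (0.116), Gm28192 (0.0660) and Tirap (0.0973) with a replicate block, and Gm28192 (0.0968) after thinning. Globin genes took 0.464% and 0.171% of neutrophil UMIs in the controls and 0.956% and 2.52% under stress. Of the 279 higher genes, 207 (74.2%) had more CPM in neutrophils than in the other cells of both stress libraries, and 72 did not. Those 72 include Ccl21a, Hspb1, Hba-a1 and these members of lists below: Hilpda, Cd63, Pcna, H2-K1, H2-Q7, Sgk1, Mt1, Ccl2, Dnajb1, Cycs, Hba-a2, Alas2 and Hbb-bt. The lower genes were not compared with the other cells in this way. Among them, Scd1 was the first leading gene of cluster 39, named alveolar type 2 cells. The fibronectin gene Fn1 was a leading gene of cluster 24, the monocytes. Whether RNA from other cells enters the falls of such genes was not tested.

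**Figure D2:**
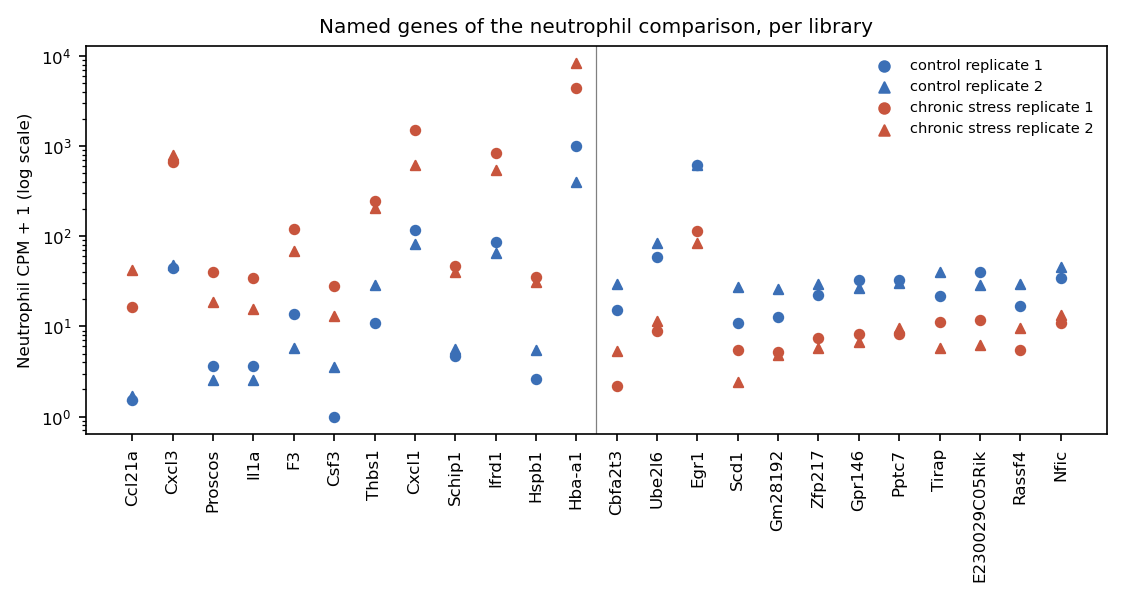
Neutrophil CPM plus 1 (logarithmic vertical axis) of the 24 genes named by the fixed rule (horizontal axis, higher genes left of the line), 1 point per library, with blue for control and red for chronic stress, circles for replicate 1 and triangles for replicate 2. Cxcl3 lies at 43.2 and 46.5 CPM in the controls and 673 and 805 CPM under stress, and Egr1 at 614 and 617 CPM against 113 and 83.2 CPM.

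By gene list, camera called 11 of 24 lists in neutrophils, none of which held with an estimated correlation (adjusted p = 0.615 with an estimated correlation). Of the 16 tested inflammatory cytokine genes, 7 rose and none fell (11 higher adjusted over the list alone), with Cxcl3, the checkpoint ligand gene Cd274 (log2 fold 2.67), Cxcl1 and Il1a in front (camera adjusted p = 2.54e-07, adjusted p = 0.615 with an estimated correlation). The list of aged and tissue-resident neutrophil genes had 4 of 14 members higher, Hilpda (2.97), Cstb (2.01), Bhlhe40 (1.92) and Spp1 (1.22), with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000517, adjusted p = 0.615 with an estimated correlation). The list of genes reported for tumour-associated suppressive neutrophils (PMN-MDSC) had 3 of 14 higher, the lectin receptor gene Clec4d (1.79), the arginase gene Arg2 (1.40) and the interleukin gene Il1f9 (1.40), with 6 adjusted over the list alone (camera adjusted p = 0.000517, adjusted p = 0.615 with an estimated correlation). Of 18 glycolysis and hypoxia genes, 1 rose, Pgam1 (1.17), with 4 adjusted over the list alone (camera adjusted p = 4.35e-06, adjusted p = 0.615 with an estimated correlation). Of 17 mature neutrophil genes, 4 rose, the formyl peptide receptor genes Fpr1 (1.59) and Fpr2 (1.22), the decoy receptor gene Il1r2 (2.09) and Slpi (1.22), with 4 adjusted over the list alone (camera adjusted p = 0.00487, adjusted p = 0.615 with an estimated correlation). Of 11 class I MHC presentation genes, 2 rose, H2-K1 (1.29) and H2-Q7 (1.28), with 2 adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.615 with an estimated correlation). Of 6 proliferation genes, Pcna rose (1.15), with 3 adjusted over the list alone (camera adjusted p = 0.0400, adjusted p = 0.615 with an estimated correlation). Called in the lower direction were mitochondrial transcripts, with 2 of 13 lower, mt-Atp8 (−1.21) and mt-Nd3 (−1.72), and 4 adjusted over the list alone (camera adjusted p = 0.000818, adjusted p = 0.615 with an estimated correlation). The 6 class II MHC genes had none passing, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0400, adjusted p = 0.615 with an estimated correlation), H2-Aa at −1.55 and H2-Eb1 at 1.59. All 5 erythroid markers rose, among them Hba-a2 (2.51), Alas2 (2.54) and Hbb-bt (2.80), also 5 adjusted over the list alone (camera adjusted p = 8.64e-06, adjusted p = 0.615 with an estimated correlation). The 11 alveolar epithelial markers were called lower with a median of −1.39 and no member passing, 0 adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.615 with an estimated correlation). Fry called 0 of 24 lists (3 at an unadjusted p under 0.05, smallest adjusted p = 0.307). Without stress replicate 1 the camera calls of the mature (0.0849), proliferation (0.422), class II (0.422) and class I (0.0545) lists ended, and without control 2 those of the proliferation (0.0571) and class I (0.0608) lists. Without stress replicate 2, 17 lists were called.

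The other 13 lists were not called in neutrophils. The pre-metastatic niche list had 3 of 15 members higher and 1 lower, Cxcl1, Csf3, Ccl2 (2.69) and the fibronectin gene Fn1 (−3.12), with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0517). In the glucocorticoid response list 3 of 18 rose, Sgk1 (1.19), Mt1 (1.94) and Cdkn1a (1.22), 3 adjusted over the list alone (camera adjusted p = 0.752), where the median was −0.05 while the mean was 0.08 and camera's direction up. In the adrenergic and cAMP response list 2 of 12 rose, Nr4a3 (2.21) and Pde4b (1.05), 3 adjusted over the list alone (camera adjusted p = 0.111). In the immediate early list of 17, Hspb1 and Dnajb1 (1.04) rose and Egr1 fell, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.502). In the type I interferon list 1 of 20 rose, Cxcl10 (1.31), 2 adjusted over the list alone (camera adjusted p = 0.752). Oxidative phosphorylation had 1 of 18 higher, Cycs (1.13), 2 adjusted over the list alone (0.0654). Of 88 ribosomal protein genes 1 rose, 0 adjusted over the list alone (0.0523), and of 9 NADPH oxidase and extracellular trap genes 0 passed, also 0 adjusted over the list alone (0.111). No member passed among the markers of B and plasma cells (7 genes, adjusted p = 0.332, median −0.05 but mean 0.27 and direction down), T and NK cells (8 genes, 0.502) or endothelial cells and fibroblasts (4 genes, 0.581), nor adjusted over the list alone.

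Differentiation state was then compared through granule genes of immature neutrophils and through mature genes. Of 14 secondary granule genes 1 rose, Olfm4 (log2 fold 1.65), 1 adjusted over the list alone (camera adjusted p = 0.120), and of 4 primary granule genes 1 rose, Cd63 (1.18), 1 adjusted over the list alone (camera adjusted p = 0.134). The log2 ratio of summed secondary granule to mature CPM was −1.87 and −1.17 in the controls and −0.91 and −1.87 under stress, or −1.52 ± 0.50 against −1.39 ± 0.68 (SD, n = 2 each). The difference of 0.13 was smaller than the spread within each group (two-sided exact permutation p = 0.667). It was −0.22 without control 1, 0.49 without control 2, −0.35 without stress replicate 1 and 0.61 without stress replicate 2. With means of log2 CPM plus 1 in place of sums it was −0.17. Sums of CPM weigh abundant genes most. Retnlg, on the mature side, held 24926 of 53802 CPM in stress replicate 1 and 5265 of 22096 CPM in control 1. Retnlg was also a leading gene of the small cluster led by Camp, Ngp and Ltf. That cluster held 16 of 1094 and 121 of 2832 control neutrophils and 158 of 5026 and 2 of 1241 stress neutrophils. Its share was thus lower in stress replicate 1 than in control 2, while Retnlg stood at 24926 and 7237 CPM there. More such cells therefore do not account for the high Retnlg of stress replicate 1 against control 2. Since a mature-side gene also led the granule cluster, the small difference does not show that differentiation state was unchanged. Among the genes reported from the fixed neutrophil set only Arg2 passed (adjusted p = 0.0409), and it did not pass without control 1 (0.129) or control 2 (0.414), at Leiden resolution 2.0 (0.0622) or with the gene length trend removed (0.0521). Log2 folds of the others were S100a8 0.58, S100a9 1.02, Ltf 0.08, Camp 1.21, Ngp 1.16, Lcn2 1.58, Mmp8 1.13, Chil3 1.09, Retnlg 1.31, Cxcr2 −0.76, Csf3r −0.18, Il1b −0.20, Cxcr4 0.59, Cd84 0.15, Fkbp5 −1.06, Tsc22d3 −0.05 and Isg15 0.67. The stress libraries disagreed in the granule genes. Camp stood at 5543 CPM in stress replicate 1 and 276 CPM in replicate 2, against 378 and 2142 CPM in the controls. Without stress replicate 2, 11 of these genes passed, with log2 folds of 1.23 for S100a8, 1.56 for S100a9, 2.21 for Camp, 2.14 for Ngp, 2.31 for Lcn2, 1.93 for Mmp8, 2.07 for Chil3, 2.07 for Retnlg, −0.88 for Cxcr2, 0.87 for Cxcr4 and −1.86 for Fkbp5. Without stress replicate 1, log2 folds were 0.30 for S100a9, 0.34 for Lcn2 and 0.32 for Cxcr4, and turned to −0.42 for S100a8, −3.00 for Ltf, −2.22 for Camp, −2.03 for Ngp, −0.50 for Mmp8, −2.42 for Chil3 and −0.07 for Retnlg, and Il1b passed at −1.16 (adjusted p = 0.00482). Fkbp5, a glucocorticoid target, passed without control 1 (−1.69, adjusted p = 0.00175) and was 0.81 without control 2.

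The same contrast in 13 other classes showed how widely genes changed. In T cells 350 genes rose and 179 fell, in B cells 202 and 48, and in NK cells 86 and 20. The named genes that rose were the transcription factor gene Maff (log2 fold 4.68), the interferon gamma gene Ifng (4.21, adjusted p = 4.83e-05) and the inducible heat shock gene Hspa1a (3.49) in T cells, Hspa1a (4.68), Atf3 (4.64) and Hspb1 (4.32) in B cells, and Hspa1a (4.17), Atf3 (3.91) and Hspa1b (3.60) in NK cells. Genes that fell were Eif3j2 in all of these, Slc34a2 (−2.96) and Dph6 (−2.03) in T cells, Rapgef4 (−2.38) and Cbr2 (−1.77) in B cells, and Mgll (−3.68) and Golga1 (−2.52) in NK cells. Slc34a2 and Cbr2 are transcripts of lung epithelium. Hspb1 rose in type 2 alveolar cells (2.79), capillary (3.70), arterial and venous (3.33) and ciliated (3.18) cells. Conventional dendritic cells had 40 genes higher, with Cxcl2 (4.48), Hcar2 (4.21) and S100a9 (3.91) in front, and pericytes and smooth muscle 10, with Wfdc17 (5.25), Cxcl2 (5.09) and S100a9 (4.69). S100a9 is among the most abundant neutrophil transcripts. Of 12 higher aerocyte genes Hba-a1 (3.87), Ccn1 (3.53) and Fos (2.57) are named, of 7 capillary genes also Milr1 (4.47) and Fam71a (0 and 2 UMIs in the controls, 151 and 115 under stress), and of 2 alveolar type 2 genes also Krtap17-1 (3.11). The cycling class is 1 cluster of 280 cells that also carries T cell markers (mean log2 fold 1.37). It had 17 genes higher, among them Hspa1b (5.58), Hspa1a (5.32) and Lyve1 (5.21), and 7 lower, among them Cbr2 (95 and 27 control UMIs), Sftpb (107 and 20) and Scd1 (45 and 10), each with 0 UMIs under stress. Some of these folds moved by over 1.5 times with 1 library left out. Without control 1 they were 6.70 for Hspa1a in NK cells and 6.33 for Hcar2 in dendritic cells, and without control 2 −1.90 for Slc34a2 in T cells and 9.93 for Fam71a. Mgll was −7.59 without stress replicate 1 and −2.33 without stress replicate 2. Without stress replicate 2, Slc34a2 was −1.42, and in B cells Atf3 was 2.83, Hspb1 2.09, Rapgef4 −1.17, Cbr2 −1.003 and Eif3j2 −9.13.

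Over the 13 classes edgeR made 982 calls, 728 higher and 254 lower, and DESeq2 3067. A replicate block gave 5039 higher and 2409 lower. In DESeq2 alveolar type 2 cells had 442 genes higher and 59 lower, against 2 calls in edgeR. Arterial and venous cells had 53 and 5 there, against 1, and pericytes and smooth muscle 59 and 5, against 10. Capillary cells, with 7 calls, had 381 with DESeq2's size factors and 1164 in DESeq2. The total was 712 without control 1, 716 without control 2, 2882 without stress replicate 1 and 2660 without stress replicate 2. T cells had 227, 162, 1251 and 1502 calls in that order, B cells 163, 212, 7 and 64, NK cells 101, 94, 263 and 84, dendritic cells 160, 127, 586 and 326, and cycling cells 0, 3, 213 and 415. Aerocytes had 49, 36, 130 and 87, pericytes and smooth muscle 0, 8, 119 and 71, capillary cells 0, 2, 14 and 20, alveolar type 2 cells 12, 0, 14 and 7, ciliated cells 0, 69, 94 and 65, and arterial and venous cells 0, 3, 2 and 5. Fibroblasts had 0 calls in edgeR (1227 higher and 719 lower at an unadjusted p under 0.05, 90 and 6 in DESeq2), with 14 without stress replicate 2. Erythroid cells had 0 as well (355 and 411 at an unadjusted p under 0.05, 24 and 0 in DESeq2), with 189 without stress replicate 1. Calls that ended without control 1, with adjusted p from 0.0503 to 0.900, were Mgll and Golga1 in NK cells, Hspb1 in arterial and venous, capillary and ciliated cells, Fam71a and Milr1 in capillary cells, Hspa1b, Hspa1a, Lyve1, Cbr2 and Sftpb in cycling cells, and Wfdc17, Cxcl2 and S100a9 in pericytes. Without control 2, with adjusted p from 0.0519 to 0.937, they were Krtap17-1 and Hspb1 in alveolar type 2 cells, Cbr2 in B cells, Mgll in NK cells, Slc34a2 in T cells, Fam71a, Milr1 and Hspb1 in capillary cells, Hspa1a, Lyve1, Cbr2, Sftpb and Scd1 in cycling cells, and Wfdc17 and Cxcl2 in pericytes. Without stress replicate 1, with adjusted p from 0.0546 to 0.228, they were Krtap17-1 in alveolar type 2 cells, Eif3j2, Rapgef4 and Cbr2 in B cells, Hspb1 in arterial and venous cells and Milr1 in capillary cells. Without stress replicate 2, with adjusted p from 0.0808 to 0.510, they were Atf3, Hspb1, Eif3j2, Rapgef4 and Cbr2 in B cells and Mgll and Golga1 in NK cells.

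Heat shock and immediate early genes, which cell dissociation is also known to induce, were compared as a list of 17. Camera called it higher in all 13 classes, with class medians of the log2 fold from 1.00 to 2.69. With an estimated correlation no class passed (adjusted p = 0.166 to 0.915 with an estimated correlation), and fry called 6 classes. Most of the members passed in 4 of the 13 classes, and none in 2. In T cells 16 of its 17 members rose (16 adjusted over the list alone), in NK cells 14 (17), in B cells 12 (16), in dendritic cells 10 (16), in cycling cells 6 of 14 (13), in aerocytes 5 (14), in capillary cells 4 (16), in pericytes and smooth muscle 2 (15), in ciliated cells 1 (17), in alveolar type 2 cells 1 (15), in arterial and venous cells 1 (14), in fibroblasts 0 (16) and in erythroid cells 0 (3). Hspb1 was called higher in 10 of the 12 classes where it was tested, and Fos and Junb in 7 of 13. In neutrophils Hspb1 rose while Fos stood at −1.85 (adjusted p = 0.0690) and Junb at −0.47. With each library's trend with gene length removed, chosen after the data were seen, camera at its preset correlation still called the list in all 13 classes, and of the 72 member calls 51 remained, 21 ended and 1 was new. In T cells the 350 higher and 179 lower genes became 282 and 73, and in B cells 202 and 48 became 149 and 33. In NK cells 86 and 20 became 71 and 26, in dendritic cells 40 and 0 became 22 and 2, and in cycling cells 17 and 7 became 9 and 8. The number of all called genes went from 12 to 2 in aerocytes, 7 to 2 in capillary cells, 10 to 0 in pericytes and smooth muscle, 2 to 0 in alveolar type 2 cells and 1 to 0 in arterial and venous cells. In ciliated cells it went from 1 to 2. For Hspb1 the log2 fold went from 2.56 to 2.15 in pericytes and smooth muscle (SE 0.29 and 0.30, adjusted p = 0.144 after), 2.79 to 2.50 in alveolar type 2 cells (SE 0.20 and 0.20, 0.0570) and 3.33 to 2.94 in arterial and venous cells (SE 0.26 and 0.27, 0.108). Smaller folds do not account for every ended call, since Peg3 in aerocytes went from 1.89 to 1.93 (SE 0.24 and 0.23, adjusted p = 0.0610 after), and the causes were not separated. The inflammatory cytokine list was called higher in 12 of 13 classes (adjusted p = 0.166 to 0.915 with an estimated correlation, fry 2), with 7 of 12 members higher in T cells (9 adjusted over the list alone). Its member Cxcl2 stood at 26843 and 19494 CPM in control neutrophils and at 113250 and 43442 CPM in stress neutrophils. Whether free RNA of neutrophils enters the calls of this list in other classes was not tested. Oxidative phosphorylation was called higher in 12 of 13 classes (adjusted p = 0.262 to 0.915 with an estimated correlation). Erythroid markers were called higher in 8 of 12 other classes (adjusted p = 0.307 to 0.665 with an estimated correlation) and alveolar epithelial markers lower in 9 of 11 (adjusted p = 0.323 to 0.672 with an estimated correlation). Over these classes and the 297 list tests, camera made 139 calls, 0 of which held with an estimated correlation, while fry made 17. All 4 libraries carry 1 batch label, so no comparison within batches separates handling from group.

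**Figure D3:**
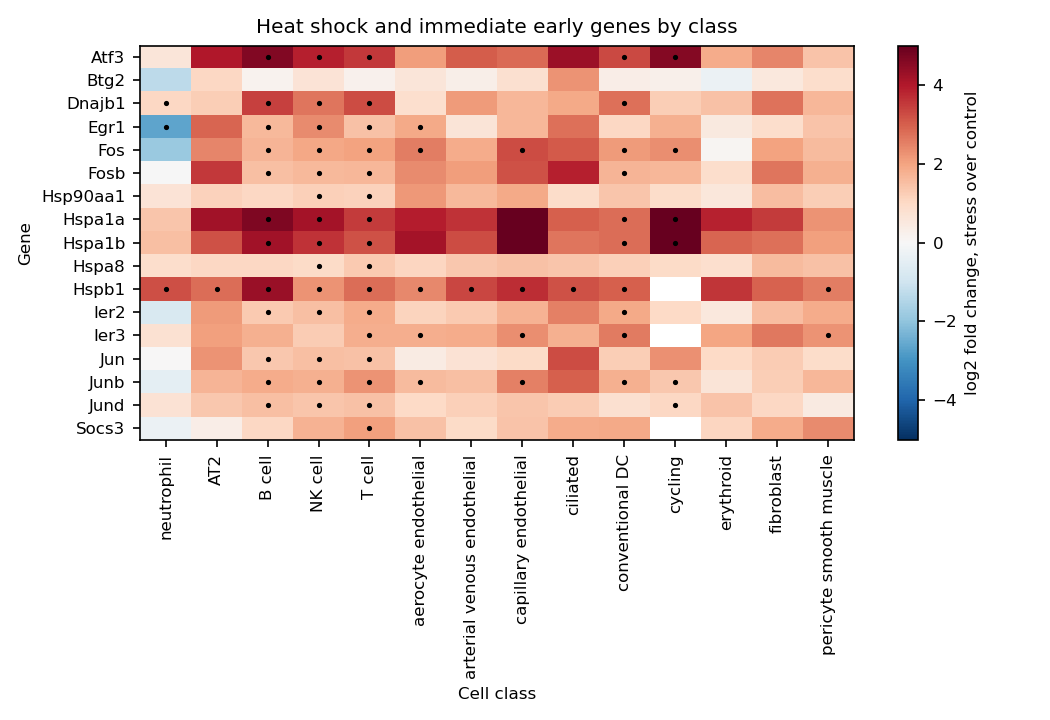
Log2 fold change of chronic stress over control (colour, red higher and blue lower, limited at 5) for the heat shock and immediate early genes (vertical axis) in each cell class (horizontal axis), with a black dot where the edgeR adjusted p was under 0.05. In T cells 16 of 17 genes carry a dot, all higher. Neutrophils carry a dot for Egr1 (−2.64), which was lower, and for Hspb1 (3.22) and Dnajb1 (1.04), which were higher.

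The translation factor gene Eif3j2 was lower in T cells (log2 fold −4.20, adjusted p = 0.000133), B cells (−4.84, adjusted p = 0.0161) and NK cells (79 and 56 control UMIs, 0 and 0 under stress). Its paralog Eif3j1 went the other way. Over 14 classes the median log2 fold was −4.45 for Eif3j2, 0.88 for Eif3j1 and 0.09 for their summed UMIs. Eif3j2 lies on chromosome 18 at 43475418 to 43477796 and Eif3j1 on chromosome 2 at 122028546 to 122056598. Over all cells, Eif3j2 took 24.1% and 65.4% of the pair's UMIs in control replicates 1 and 2 and 1.39% and 1.60% in the stress libraries, so the controls differed from each other as well. In B cells the Eif3j2 call ended without stress replicate 1 (adjusted p = 0.221) and without stress replicate 2 (0.299). The pair may share reads, which were not examined, so each gene's own value is uncertain.

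**Figure D4:**
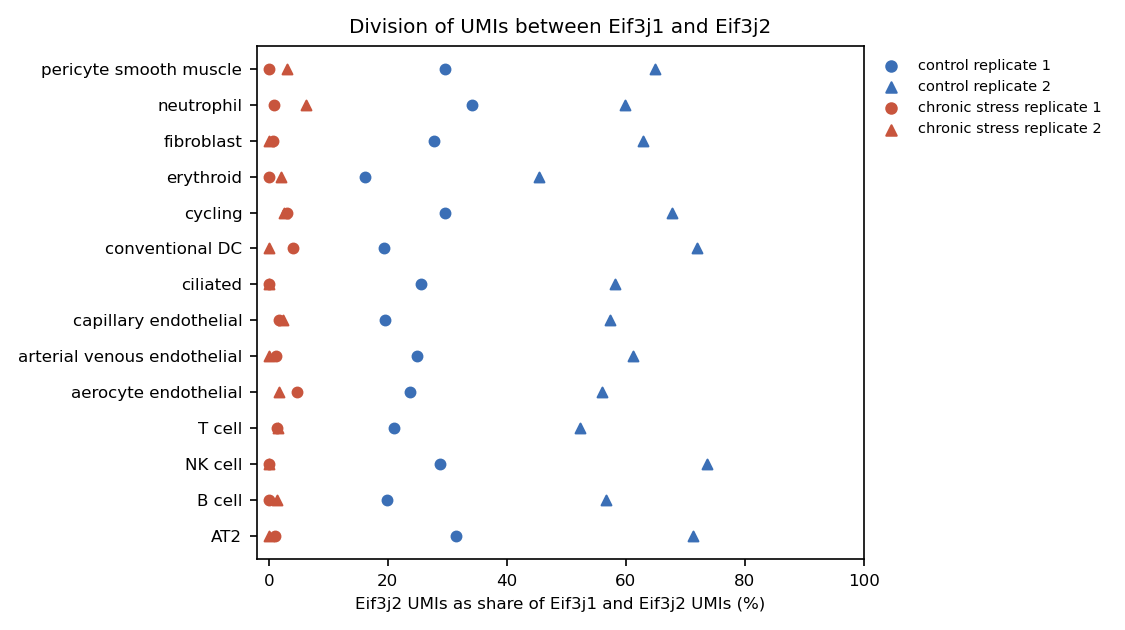
Share of Eif3j2 in the summed UMIs of Eif3j1 and Eif3j2 (%, horizontal axis) for each cell class (vertical axis), 1 point per library, with blue for control and red for chronic stress, circles for replicate 1 and triangles for replicate 2. Class shares lay from 16.1% to 34.1% in control 1, from 45.5% to 73.7% in control 2, and at or below 4.65% and 6.25% in the stress libraries.

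The last comparison looked for mammary tumour cells in the lung. No cluster was named as tumour epithelium in any library, but a named cluster needs at least 20 cells, so smaller groups of tumour cells are not excluded. Cluster 45 (22, 7, 20 and 46 cells in controls 1 and 2 and stress replicates 1 and 2) was led by the milk genes Csn3 and Wfdc18, next to muscle genes (Acta1, Tnnc2) and type 1 alveolar genes (Ager, Hopx). It stayed unnamed, because markers of a second lineage passed the limit, and 13 of its 95 cells held UMIs of the PyMT transgene. By a rule on single cells chosen after the data were seen (UMIs of Epcam, of Krt8 or Krt18, and at least 3 of the milk genes Csn3 and Wfdc18), 14 and 1 control cells and 1 and 2 stress cells qualified, or 0.0279% of all cells. Of these 18 cells, 14 lay in cluster 45 and 17 held UMIs of the transgene. Their exact 95% intervals were 0.0359% to 0.110% in control 1, 0.000160% to 0.0352% in control 2, 0.000179% to 0.0394% in stress replicate 1 and 0.00183% to 0.0546% in stress replicate 2. The groups overlapped and the controls differed from each other, so no difference between groups is claimed, and none was tested.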

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

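Chosen only after the results were seen were the comparison of neutrophils with T cells, the position test of lowered genes, and the tests on the handling of libraries, on RNA bounded by neutrophils, on a variant at Eif3j2, and on gene length in erythroid cells. The measures of spread beside the test of free RNA, and the calls with the gene length trend removed, were also added afterwards.

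The stress effect differed between neutrophils and T cells for 12 of 17 immediate early genes, lower in neutrophils for all 12, by an edgeR interaction test over 10775 genes with 170 calls. For 5 of them the log2 folds had the same sign in both classes, with log2 differences (neutrophil effect minus T cell effect) of −2.31 for Hspa1a, −2.11 for Dnajb1, −2.88 for Atf3, −1.79 for Hspa1b and −1.38 for Jun. For the other 7 they had opposite signs, though Fosb stood near 0 in neutrophils (−0.022). Their log2 differences were −4.04 for Egr1, −3.85 for Fos, −2.58 for Ier2, −2.79 for Junb, −2.48 for Socs3, −1.57 for Fosb and −1.47 for Btg2. Of these 7, only Egr1 passed in neutrophils on its own (−2.64), while in T cells all but Btg2 passed.

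Camera called the heat shock and immediate early list higher in all 13 classes other than neutrophils (adjusted p = 0.166 to 0.915 with an estimated correlation), with most of its members passing in 4 classes and none in 2. In neutrophils it was not called (camera adjusted p = 0.502), but members moved both ways there, with 10 of 17 positive. The heat shock genes had positive log2 folds (Hspb1 3.22, Hspa1b 1.51, Hspa1a 1.37, Dnajb1 1.04, Hspa8 0.87, Hsp90aa1 0.68), of which Hspb1 and Dnajb1 passed. Egr1 (−2.64), Fos (−1.85), Btg2 (−1.31) and Ier2 (−0.74) were negative, of which Egr1 passed. The missing call thus does not show that neutrophils lacked a heat shock rise. RNA from other cells that carries Hbb-bs from 1 source would keep the list's excess over control in 1 ratio to the Hbb-bs excess. Yet this ratio spanned 6.46-fold over classes in stress replicate 1 and 5.483-fold in replicate 2 (counting intervals 5.98 to 6.94 and 5.17 to 5.81). Against single controls it spanned 5.85 to 30.0-fold. Left out were 3 of 12 classes in stress replicate 1 and 2 in replicate 2 with no Hbb-bs excess. Gene length, taken as genomic span, is argued against as the whole cause, while transcript length was not tested. A trend with length was present in every class, with longer genes lower under stress. Its correlation with the log2 fold ran from −0.47 in capillary cells to −0.11 in erythroid cells, and was −0.24 in neutrophils. Between replicates of a group it ran from −0.089 to 0.23. With the trend removed, the median over classes kept 80.23% of its size (1.81 to 1.45, from 77.8% to 91.5% in 12 classes). Camera at its preset correlation still called the list in all 13 classes, but before the removal none of its calls held with an estimated correlation. Gene length stays open in erythroid cells, which kept 58.38% (1.00 to 0.58). In all, 21 of the 72 member calls ended, such as Hspb1 in pericytes (2.56 to 2.15, SE 0.29 and 0.30), alveolar type 2 cells (2.79 to 2.50, SE 0.20 and 0.20) and arterial and venous cells (3.33 to 2.94, SE 0.26 and 0.27), with smaller folds at a similar SE. Free RNA from other sources stays open, because the excess was above the neutrophil level for a median of 52.94% of members. With 1 batch label, handling of the libraries cannot be told apart from stress, and a response to stress itself may be biological but is untested.

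Eif3j2 was among 97 genes lower without overlap in at least 3 classes. In each of these classes they were more than 2-fold lower, at an unadjusted edgeR p under 0.05 and a mean of at least 10 CPM. A strain or donor variant in 1 region is argued against as the cause for most of them. The fullest 10 Mb window held 4 of the 97 genes, with a median of 4 in 10000 random draws (permutation p = 0.799). The 97 also include lung epithelial transcripts such as Slc34a2 and Cbr2, and a variant that touches only a few genes is not excluded. For Eif3j2 alone, reads shared between paralogs are a candidate explanation, since the summed UMIs of the pair had a median log2 fold of 0.09371 where Eif3j2 had −4.45 and Eif3j1 0.88. A variant at Eif3j2 stays open, since the lowest class share in control 2 lay 11.36 percentage points above the highest in control 1, which read mapping that differs between libraries would give as well. No biological explanation was tested for this pattern.

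Among the genes called in neutrophils, more were higher than lower under stress, 279 against 96. At an unadjusted p under 0.05 in edgeR it was 967 against 874, so only the genes past the adjusted limit carried the excess. Under the first, unrelaxed naming rule the calls were 287 against 136 (67.8% higher) with doublets kept. They turned to 423 against 530 (44.4%) with stricter filters, where few stress neutrophils were named (381 and 32). With the gene length trend removed 82.8% of calls were higher, and after thinning to the smallest library 75.83%, so gene length and depth are argued against as the whole cause. With DESeq2's size factors the share was 80.76%. Both scalings assume that most genes are unchanged, so this swap cannot decide on scaling. Without the low-count filter the share was 63.0%. RNA from other cells stays open, since 74.19% of the higher genes stood above the other cells of both stress libraries. A biological effect of stress may also underlie the excess, but it is untested and stays open next to handling, which shares its groups.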

How the results depend on the processing

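Chosen after seeing the data were removal of the gene length trend, the single-cell tumour rule and the relaxed naming rule used throughout, beside which its first, unrelaxed form was then run, while the other alternatives were fixed before. Over all alternatives the named genes, lists and class counts stayed on their side of the threshold 857 times, with 121 weaker, 34 stronger, 64 moved and 28 reversed, and the cause was not tested unless fewer samples are named. Neutrophil genes higher and lower (279 and 96) numbered 578 and 340 without the low-count filter, 188 and 48 at Leiden resolution 2.0, 390 and 49 in DESeq2, 207 and 43 with the gene length trend removed, 287 and 136 under the unrelaxed naming rule with doublets kept, 423 and 530 under it with stricter filters, and 45 to 998 and 7 to 505 with 1 library left out. A replicate block, for which the shared numbers show no pairing (correlations of −0.23 to 0.40 over classes, −0.08 in neutrophils), gave 218 and 36, and 7448 genes in other classes. Other class genes (982) numbered 3067 in DESeq2 and 712 to 2882 with 1 library left out. Neutrophil lists (11) numbered 0 with an estimated correlation or fry and 12 to 17 with 1 library left out, and those of other classes (139) 0 and 17. Shares passing were 2 with doublets kept. The neutrophil share log2 fold ran from −0.30 to 2.13 with 1 library left out, and was −3.51 (doublets kept) and −2.74 (stricter filters) under the unrelaxed naming rule. The tumour-like share was 0.0279% by the single-cell rule. Reversed values with 1 library left out ran from −0.42 to 1.23 for S100a8, −3.00 to 1.40 for Ltf, −2.22 to 2.93 for Camp, −2.03 to 2.22 for Ngp, −0.50 to 1.93 for Mmp8, −2.42 to 2.48 for Chil3, −0.073 to 2.07 for Retnlg, −1.16 to 0.43 for Il1b, −0.033 to 0.38 for Cd84, −1.86 to 0.81 for Fkbp5 and −0.32 to 0.33 for Tsc22d3. Ltf was −0.56 with the block, −0.094 with stricter filters, −0.27 at resolution 2.0 and −0.028 thinned. Tsc22d3 was 0.0047 with stricter filters and 0.14 with the trend removed. Under the unrelaxed naming rule with doublets kept and with stricter filters, Cxcr4 was −1.49 and −1.17, Cd84 −0.88 and −0.72 and Isg15 −1.42 and −1.34, and Arg2 was −0.11 with doublets kept. At this depth, 26% of genes changed 2-fold, drawn from those of at least 10 CPM, were recovered in simulated neutrophil counts (7707 genes).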

Other observations

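In T cells 5 of 11 cytotoxic lymphocyte genes rose (7 adjusted over the list alone), among them Ifng, Nkg7 (log2 fold 1.01), the death ligand gene Fasl (1.05) and the granzyme gene Gzmb (2.21), with a camera adjusted p = 0.000263 and an adjusted p = 0.427 with an estimated correlation. Cluster 11, the T cells led by Ccl5, Xcl1, Ifng and Nkg7, made up 10.8% and 13.7% of control T cells and 26.4% and 15.9% of stress T cells, and the effect of this makeup on the list was not tested. In NK cells 1 of 10 rose, Ifng (3.11), 3 adjusted over the list alone (camera adjusted p = 0.00105, adjusted p = 0.323 with an estimated correlation), and in erythroid cells the list was called lower with no member passing (3 lower adjusted over the list alone, camera adjusted p = 0.0437, adjusted p = 0.915 with an estimated correlation). Of 7 T cell checkpoint genes 0 passed in T cells, 1 adjusted over the list alone (camera adjusted p = 0.320), and 0 of 5 in cycling cells (0.402). In T cells 7 of 18 glucocorticoid response genes rose (8 adjusted over the list alone), among them the phosphatase gene Dusp1 (2.21), Zfp36 (1.51), Sgk1 (1.36) and the clock gene Per1 (2.45), with a camera adjusted p = 5.76e-07 and an adjusted p = 0.427 with an estimated correlation. Of the 12 adrenergic and cAMP response genes 9 rose in T cells (9 adjusted over the list alone), Nr4a1 (2.24), Nr4a2 (2.39) and Ppp1r15a (1.57) among them, with a camera adjusted p = 1.78e-10 and an adjusted p = 0.427 with an estimated correlation. Immediate early genes rose in the same T cells, and Dusp1, Zfp36, Nr4a1 and Nr4a2 are themselves early response genes.

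Over the other classes, camera called further lists, none of which held with an estimated correlation (smallest adjusted p = 0.166 with an estimated correlation). Whether free RNA of neutrophils enters the calls of neutrophil gene lists in these classes was not tested. Called higher in 6 of 13 classes was the glucocorticoid list (adjusted p = 0.323 to 0.511 with an estimated correlation), and in 7 of 12 the adrenergic list (adjusted p = 0.166 to 0.719 with an estimated correlation). Of 13 classes, PMN-MDSC genes were called higher in 9 (0.307 to 0.672), proliferation in 9 (0.342 to 0.915), ribosomal protein genes in 9 (0.486 to 0.884) and glycolysis and hypoxia in 6 (0.307 to 0.672), with the adjusted p with an estimated correlation in brackets here and below. Aged and tissue-resident neutrophil genes were called higher in 6 (0.307 to 0.915) and class I MHC genes in 5 (0.323 to 0.550) of 13, and mitochondrial transcripts lower in 5 (0.307 to 0.575). The pre-metastatic niche list was called higher in 7 of 12 (0.307 to 0.672). Class II MHC genes were called higher in 2 (aerocytes and ciliated cells) and lower in 2 (T and NK cells) of 12 (0.323 to 0.492). The mature neutrophil list was called higher in 2 of 13 (dendritic cells and pericytes, 0.262 to 0.432), secondary granule genes (0.441) and interferon genes (0.915) in 1 each, and the NADPH oxidase list in 2 of 12 (0.307 to 0.323). The alternatively activated macrophage list was called in 0 of 5 classes, the macrophage markers in 0 of 4 and T and NK markers in 0 of 11. B and plasma markers were called lower in 1 of 8 (0.551), endothelial and fibroblast markers higher in 1 of 6 (0.307), and mammary tumour markers higher in 1 of 2 (alveolar type 2 cells, 0.575).

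UMIs of the PyMT transgene numbered 120 and 16 in the controls and 14 and 38 under stress, of which the tumour-like cells held 71, 1, 1 and 8. At least 1 UMI was found in 0.277% and 0.0947% of control cells and 0.0849% and 0.227% of stress cells, or 0.216%, 0.0884%, 0.0779% and 0.212% without the tumour-like cells. Leaving out the tumour-like cells, by class it was found in 38 of 13843 T cells (median 2021 UMIs per cell), 11 of 2419 NK cells (1701), 9 of 854 conventional dendritic cells (6010), 5 of 160 plasma cells (10340), 24 of 2428 unnamed cells (2676), 0 of 10193 neutrophils (1415), 1 of 6702 alveolar type 2 cells (5430) and 0 of 9669 capillary cells (1953). Libraries with more of the transgene weigh differently in each class, so these totals do not compare classes. In control 1, control 2, stress replicate 1 and stress replicate 2 it was found in 17 of 6768, 6 of 1675, 5 of 902 and 10 of 4498 T cells, and in 0 of 1094, 2832, 5026 and 1241 neutrophils. A count of 0 allows up to 0.274% and 0.106% of control neutrophils and 0.0597% and 0.242% of stress neutrophils, against T cell shares of 0.251%, 0.358%, 0.554% and 0.222%. A difference between these classes was not tested, and neutrophils hold fewer UMIs per cell.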
